A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

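RNA was sequenced from 12 cultures of budding yeast (Saccharomyces cerevisiae, W303, mating type a). In all of them the chromosomal SCC2 gene carried an auxin-inducible degron tag, and the plant F-box protein OsTIR1, which targets such tags for degradation, was expressed from the ADH1 promoter. SCC2 encodes a subunit of the complex that loads cohesin, the ring that holds sister chromatids together, onto chromosomes. Each strain also carried a HIS3 plasmid holding wild-type SCC2 (WT), scc2 with the R787G change, scc2 with the G1242V change, or no SCC2 insert (called null in the labels and empty_vector here), with 3 libraries per group. Per the labels, cultures were grown overnight without histidine, diluted to an OD600 near 0.1, grown for 90 min and treated with 1 mM auxin for 3 h, to an OD600 of 0.4 to 0.8. RNA was extracted with hot acid phenol, depleted of ribosomal RNA, made into stranded libraries and sequenced as 50 bp single reads. The growth protocol speaks of duplicates for the null strain, while the table and the series design hold 3 libraries, and all 3 were used.

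The deposited table gives TPM, transcript abundances scaled to a fixed total per library, which the authors computed with RSEM. Their processing notes name bcl2fastq 2.17, STAR, RSEM, edgeR and the sacCer3 genome, without stating which step each of the last programs served. TPM keeps no read counts, so the depth of each library is unknown and no counting intervals or detection floors are given. TPM summed to between 999546 and 999718 per library, and between 6480 and 6587 features were above 0. The table holds 7036 features. In 3 of them a comma in the gene symbol (DUR1,2, ARG5,6 and ADE5,7) had shifted the values by a field, and these were left out, as was 1 unnamed column. Of the 7033 features used, 184 were at 0 in every library and 248 had values identical to those of another feature. Locus tags matched 5953 features to the reference annotation, symbols or synonyms matched 169, and 911 were not matched. Coordinates are from the R64 reference annotation; the table itself holds none, so the builds could not be compared on the file. Whether reads on the opposite strand were excluded is not stated.

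TPM was scaled per library by a median-of-ratios factor over 5421 genes with a mean TPM of 10 or more and no zero; the factors ranged from 0.904 to 1.19. The 6097 features with a mean TPM of 1 or more were tested on log2(scaled TPM + 1) with limma 3.58.1 (variance trend, moderated two-sided test, R 4.3.3, statmod 1.5.0). All 12 libraries were fitted together with the group as the only term, which left 8 residual degrees of freedom plus 3.20 from the prior. P-values were adjusted per comparison by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Levels are means of scaled TPM ± SD over 3 libraries, and SE is that of the log2 fold change. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so none is given for single genes.

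Gene lists were tested with camera (preset correlation 0.01) where at least 5 members were tested. Of 38 lists with members in the table, 37 were tested; the tRNA list had only 3 tested members. Camera's adjusted p is over the 37 lists of a comparison. Counts of list members are over all genes tested, with those adjusted over the list alone beside them. Every list was also tested with an estimated correlation and with fry, which asks whether a list's own genes move, on balance, one way. Genes within 25 kb of a centromere, within 25 kb of a chromosome end, or within 1 kb of a tRNA gene were tested as position sets. Their adjusted p is over these sets of a comparison alone.

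Lists, comparisons, test, thresholds and the rule for named genes were fixed before the data were examined. The rule took, against WT, the 8 largest rises and 8 largest falls among called genes with a mean TPM of 5 or more and no overlap between the groups. Between the other groups it took 5 of each, and where no gene was called, the 5 of smallest p. It added up to 4 members of each list that passed camera against WT, SCC2, HIS3, and the cohesin and loader genes. Some genes that the rule took are not reported here.

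The likeness of 2 comparisons against WT was measured across genes by Pearson's r, Spearman's rho and the covariance. Because the comparisons share the WT libraries, each value stands beside the mean of 100 simulations in which neither group differed from WT. These draw libraries and genes independently, so they leave out deviations shared by libraries of equal number, such as those of WT and R787G below. The size of each mutant effect along the empty_vector effect is a slope across genes, with the shared WT variance and the noise removed. Replicate numbers did not pair the libraries throughout: of 18 pairs with equal numbers, 8 had deviations correlated above 0.1, among them all 3 of WT with R787G (0.199, 0.146 and 0.468), and 6 of the 12 libraries correlated best with their own number. A replicate block was therefore an alternative only. With it R787G against WT gave 0 calls, as without. That block was common to all 12 libraries, while the other pairs with equal numbers did not all share deviations. It may thus leave in the deviations that WT and R787G share, and it does not decide whether pairing them would give calls. A paired fit of WT and R787G alone was not run.

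The alternatives were TPM as deposited, quantile normalization, protein-coding genes only, pseudocounts of 0.1 and 5, no filter, a filter at a mean TPM of 10, a replicate block, a fit to only the 2 groups compared, no variance trend, a robust variance, and leaving out each library in turn. Added after seeing the data were leaving out libraries 1 and 3 labelled G1242V, leaving all 3 libraries labelled G1242V out of the fit, counting identical features once, and fry.

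The procedure was tested on simulated data with 200 changed genes, the noise being independent between genes. At 1.5-fold and at 2-fold, 97.0% of 67 genes each were called, and at 4-fold 100% of 66. The changed genes were drawn only from features with levels well above the filter, and the libraries were independent, with moderated variances. These shares therefore do not say how many changes of such size the real comparisons could miss. Of 210 calls, 14 were genes that had not been changed, and an unchanged comparison gave 0 calls. A slope simulated at 0.5 was recovered as 0.503. In a preliminary run the list meant to be unshifted held some of the changed genes; it was redrawn from unchanged genes with the same seed, after which camera gave an adjusted p of 0.301.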

Results

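The data are the RNA levels of 6097 tested features in 12 yeast libraries, 3 for each of the plasmids WT, R787G, G1242V and empty_vector, all sampled 3 h after auxin was added to degrade the chromosomal Scc2 protein. Read depth is unknown, because only TPM was used. Spearman correlations over features were 0.985 to 0.995 within groups and 0.967 to 0.995 between groups. The first principal component held 37.8% of the variance, the second 17.0%. SCR1, the RNA of the signal recognition particle, took 7.07% to 15.5% of all TPM, with the lowest share in empty_vector library 3.

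SCC2 RNA (YDR180W, chromosome IV, 821295 to 825776) was measured first, as a check on which plasmid each culture carried; reads from the degron-tagged chromosomal copy and from the plasmid copy are summed. Its level was 119 ± 9.57 scaled TPM in WT, 92.1 ± 6.75 in R787G and 12.4 ± 0.353 in empty_vector (SD, n = 3). The 3 libraries labelled G1242V differed from each other: SCC2 stood at 51.2 in library 1, 93.2 in library 2 and 12.4 in library 3. HIS3 (YOR202W, chromosome XV, 721946 to 722608), the plasmid's selection marker and a histidine synthesis enzyme, was at 847 ± 52.0 in WT, 1091 ± 243 in R787G and 2838 ± 580 in empty_vector. In the libraries labelled G1242V it was at 2498, 1042 and 2780. Library 3 labelled G1242V thus had the SCC2 and HIS3 levels of empty_vector, library 2 had levels near those of R787G, and library 1 lay between them in SCC2.

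**Figure D1:**
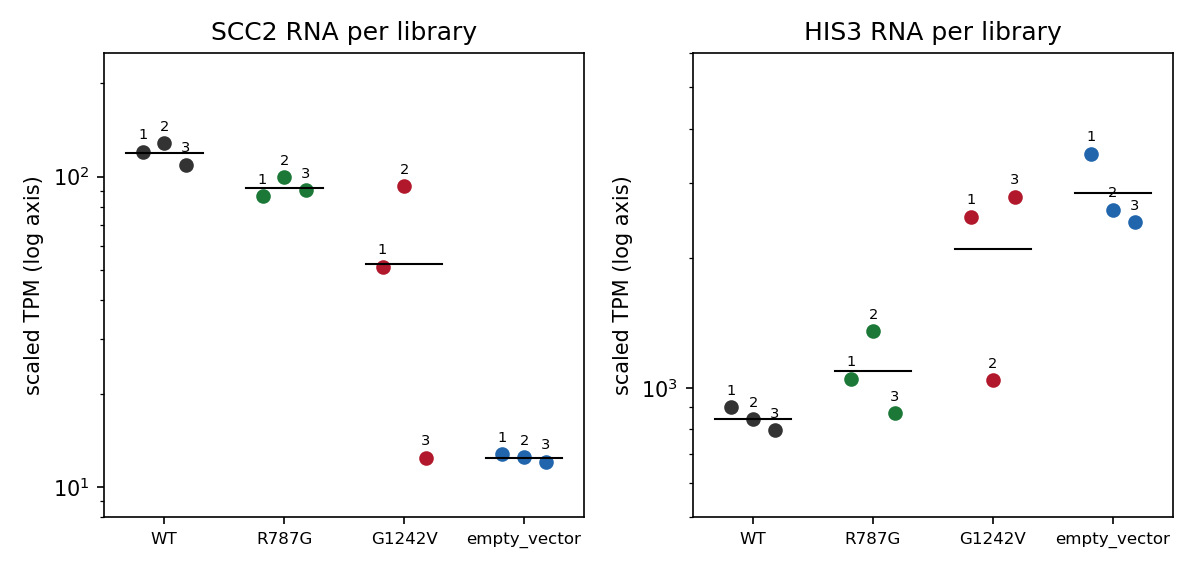
SCC2 and HIS3 levels (scaled TPM) in each of the 12 libraries by group, with replicate numbers beside the points and lines at the group means. SCC2 in the libraries labelled G1242V runs from 12.4 to 93.2, while the empty_vector libraries lie between 12.1 and 12.8.

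The comparison of empty_vector with WT asks what loss of Scc2 does to the transcriptome within 3 h. WT here is not a strain with SCC2 RNA at the chromosomal level. It held 109 to 128 scaled TPM of SCC2, against 12.1 to 12.8 in empty_vector, where only the chromosomal copy is present. SCC2 fell by 3.16 on the log2 scale (SE 0.50, adjusted p = 0.0440), and HIS3 rose by 1.73 (SE 0.31, adjusted p = 0.0440) together with YOR203W, a reading frame outside the reference annotation (1.75, SE 0.30). SWI5, a transcription factor of late mitosis, stood at 31.1 ± 0.706 in WT and fell by 1.20 on the log2 scale (SE 0.20). CDC5, the polo kinase, went from 21.9 ± 1.09 to 13.9 ± 0.429 (-0.63), and DSE1, a daughter-cell gene, from 57.8 ± 6.31 to 22.1 ± 4.48 (-1.36). The hexose transporter gene HXT5 rose from 90.2 ± 10.6 to 167 ± 40.2 (0.86), and NRG2, a repressor in glucose signalling, from 39.0 ± 6.95 to 69.6 ± 13.9 (0.82). Ribosomal RNA of 25S and 18S, which the library protocol depletes, was lower as well (-2.03 and -1.75). The RNA quality and depletion list had 8 of 15 members lower, and 10 when adjusted over the list alone (median -1.23, camera adjusted p = 1.36e-07, adjusted p = 0.440 with an estimated correlation). Its members vary together (estimated correlation 0.463) and include repeated ribosomal RNA loci, so they are not separate observations in any comparison. Of the 161 features called here, 8 had values identical to those of another feature.

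Of the 35 tested members of the G2/M list (the CLB2 cluster), 18 fell, none rose and 17 did not pass; adjusted over the list alone, 26 fell and 1 rose. Among those that fell were ALK1, a haspin-like kinase (-0.94, SE 0.13), and CHS2, the chitin synthase of the septum (-1.07, SE 0.18). The list's median was -0.45 (camera adjusted p = 1.27e-11, adjusted p = 0.440 with an estimated correlation). The M/G1 list (genes of the passage from mitosis to G1) had 6 of 34 members lower and none higher, 14 lower when adjusted over the list alone, with a median of -0.27 (camera adjusted p = 4.85e-06, adjusted p = 0.440 with an estimated correlation). Its members SCW11, a cell wall glucanase (-1.23, SE 0.28), SUN4, a septation gene (19.9 ± 2.32 against 40.7 ± 3.53), and RAX2, a bud site gene (-0.57, SE 0.11), fell. In the G1/S list 4 of 48 members fell, among them MCD1, the cohesin kleisin (-0.64, SE 0.12), and RNR1, a ribonucleotide reductase subunit (-0.57, SE 0.13); adjusted over the list alone 12 fell and 3 rose. That list's median was -0.14 (camera adjusted p = 0.00262, adjusted p = 0.440 with an estimated correlation). Of the 12 cohesin and loader genes, SCC2, which the empty plasmid lacks, and MCD1 fell. The other 10 did not pass, among them SMC1 (-0.13, SE 0.06), SMC3 (-0.15, SE 0.06) and PDS5 (0.23, SE 0.06). Adjusted over the list alone 2 rose and 2 fell; the list as a whole did not pass (adjusted p = 0.483).

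Targets of Gcn4, the activator of amino acid synthesis, had 9 of 57 members higher and none lower, 17 higher when adjusted over the list alone (median 0.12, camera adjusted p = 9.73e-06, adjusted p = 0.440 with an estimated correlation). By library the median was -0.02, 0.29 and 0.18, so library 1 showed no rise. ARO1, of aromatic amino acid synthesis, rose by 0.64 (SE 0.14). ARG7, of arginine synthesis, rose by 0.49 (SE 0.10) and HOM3, of threonine and methionine synthesis, by 0.43 (SE 0.09). No member of the proteasome list was called, but 29 of 33 were lower when adjusted over the list alone (median -0.43, camera adjusted p = 1.27e-11, adjusted p = 0.440 with an estimated correlation). Its members vary together (estimated correlation 0.887), so they are not separate observations. By library the proteasome median was -0.28, -0.56 and -0.45 in empty_vector, while WT ran from -0.17 to 0.24 and R787G from -0.28 to 0.25. Among chaperone targets of Hsf1, 1 of 22 fell, HSP10, the mitochondrial co-chaperonin (-0.87, SE 0.19); adjusted over the list alone it was 12 (median -0.38, camera adjusted p = 1.15e-06, adjusted p = 0.442 with an estimated correlation). In the ribosome biogenesis list 3 of 97 members fell, UTP23 (-0.41), UTP13 (-0.33) and RRP5 (-0.26), and 22 when adjusted over the list alone (median -0.16, camera adjusted p = 1.27e-11, adjusted p = 0.440 with an estimated correlation).

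In all, 16 of 37 lists passed camera, 3 higher and 13 lower; with an estimated correlation 0 passed, and with fry 7. Limma called 161 features, 69 higher and 92 lower, with 3 higher and 23 lower by at least 2-fold; 1747 had an unadjusted p under 0.05, where 305 were expected by chance. The groups did not overlap at 2176 features (35.7%, where chance gives 10%). The smallest adjusted p was 0.0406, and the count fell to 24 without empty_vector library 1 and to 0 without each of the other 5 libraries in turn, with no filter, with a replicate block or with no variance trend. In the 6 fits without 1 of these libraries the calls of SCC2 and HIS3 were lost while the folds stayed, from -3.22 to -3.10 (SCC2, empty_vector against WT) and from 1.57 to 1.83 (HIS3, empty_vector against WT). Their SE is pooled over all groups, the unequal libraries labelled G1242V included, and both calls held with these left out of the fit. With TPM as deposited 154 of 206 calls were higher, and with quantile normalization 82 of 151, against 69 of 161 here.

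**Figure D2:**
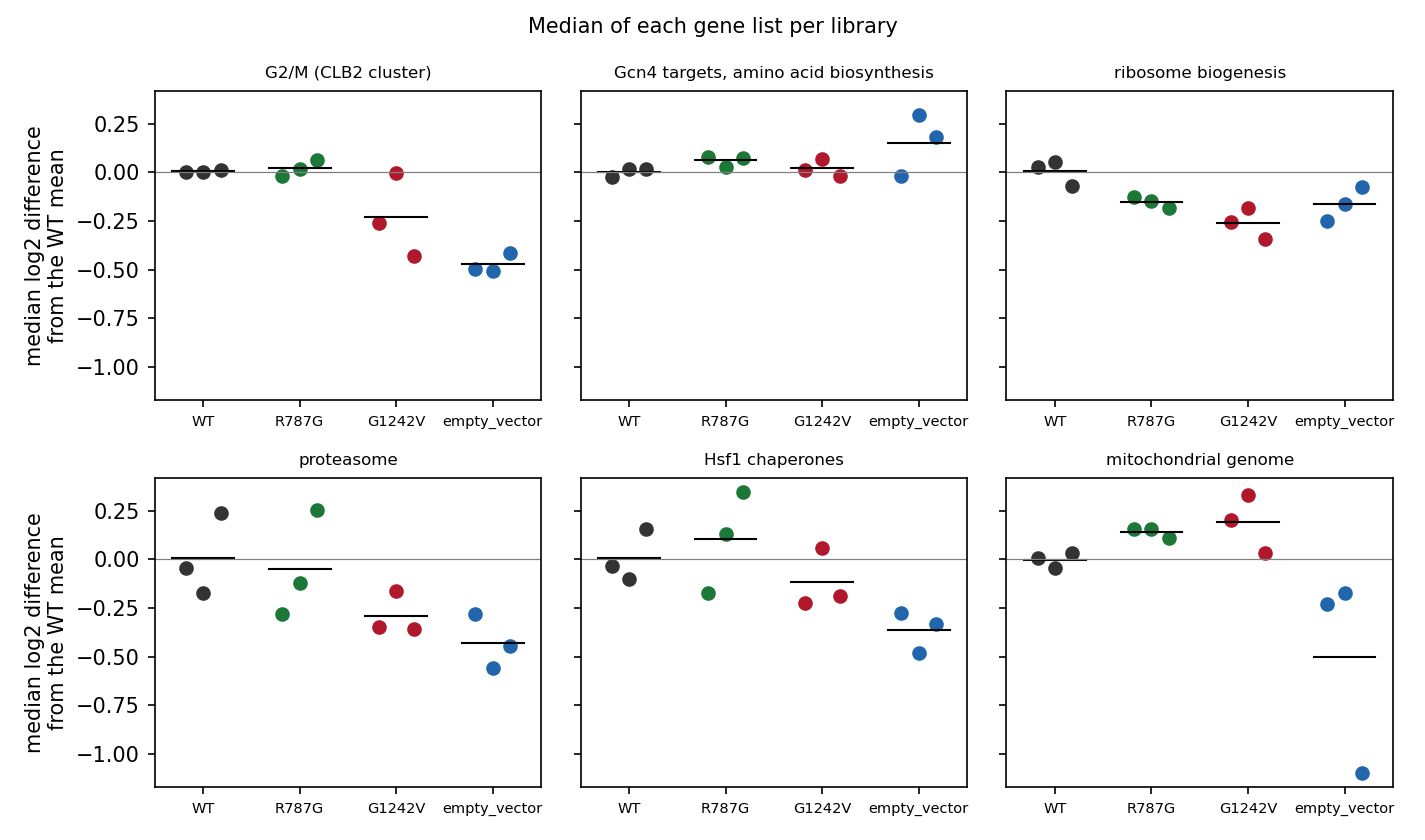
Median log2 level of gene lists in each library, relative to the WT mean, by group. The G2/M list lies between -0.51 and -0.41 in the empty_vector libraries and between -0.02 and 0.06 in the R787G libraries, and it runs from -0.43 to -0.01 in the libraries labelled G1242V.

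The R787G comparison with WT asks which transcripts this change in Scc2 alters when it is the only intact source of the protein. No gene was called by limma. The 5 genes of smallest p, each with an adjusted p of 0.122, were BDH1, a butanediol dehydrogenase (196 ± 9.70 against 147 ± 6.77), LEU2, of leucine synthesis (103 ± 0.657 against 67.3 ± 4.83), VHS1, a kinase gene (105 ± 4.38 against 77.7 ± 6.37), the subtelomeric helicase gene YRF1-8 (9.81 ± 1.20 against 5.75 ± 0.656), and RDN25-1, a copy of the 25S ribosomal RNA gene (177 ± 34.9 against 779 ± 199). Members of the ribosome biogenesis list lay below WT in 96 of 97 cases, with a median of -0.16 (camera adjusted p = 7.04e-35, adjusted p = 0.267 with an estimated correlation). None of them passed over all genes and 8 were lower when adjusted over the list alone; LCP5 was at 33.5 ± 1.19 against 41.5 ± 1.89 and NSR1, a nucleolar protein, at 181 ± 11.3 against 222 ± 13.7.

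Stress genes driven by Msn2 and Msn4 had a median of 0.15 in R787G, with 42 of 53 members above WT and none called in either count (camera adjusted p = 5.06e-10, adjusted p = 0.0900 with an estimated correlation). GPH1, glycogen phosphorylase, was at 191 ± 23.7 against 136 ± 15.0, and GSY2, glycogen synthase, at 185 ± 13.4 against 145 ± 6.93. The M/G1 list lay above WT, at a median of 0.13 (camera adjusted p = 0.00949, adjusted p = 0.696 with an estimated correlation), and the G2/M list at 0.01 (camera adjusted p = 0.843); neither had a member called in either count. None of the 12 cohesin and loader genes passed in either count; MCD1 had a log2 fold of -0.06 (SE 0.12) and SCC2 itself -0.37 (SE 0.50, adjusted p = 0.972). That SE is pooled with the unequal libraries labelled G1242V; the SCC2 levels of R787G and WT did not overlap, but with the libraries labelled G1242V left out of the fit SCC2 did not pass either.

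Of 37 lists 12 passed camera, 9 higher and 3 lower; with an estimated correlation 0 passed, and with fry 0. RNA quality and depletion features were among the lower, with a median of -0.48, none of 15 called and 4 lower when adjusted over the list alone (camera adjusted p = 1.80e-06, adjusted p = 0.378 with an estimated correlation). Across the genome 419 of 6097 features (6.87%) had an unadjusted p under 0.05 between R787G and WT, where 305 were expected by chance. The groups did not overlap at 800 features (13.1%, where chance gives 10%). The count of 0 became 5 without the libraries labelled G1242V in the fit and 3 when only the 2 groups were fitted.

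The comparison of the libraries labelled G1242V with WT asks the same of the other change, with the unequal SCC2 levels given above. Ribosome biogenesis genes fell: NOP1, the fibrillarin methyltransferase, from 92.9 ± 2.83 in WT to 62.6 ± 3.90 (log2 fold -0.56, adjusted p = 0.0116), GAR1, of the H/ACA snoRNPs, from 66.4 ± 1.56 to 48.5 ± 2.84 (-0.45), and RSA4, a 60S assembly factor, from 22.8 ± 0.985 to 13.8 ± 2.43 (-0.70, adjusted p = 0.0109). Of the 97 members of the ribosome biogenesis list, which does not hold RSA4, 34 fell, none rose and 63 did not pass. Adjusted over the list alone 69 fell (median -0.26, camera adjusted p = 2.97e-27, adjusted p = 0.448 with an estimated correlation). Among RNA polymerase I and III genes 3 of 35 fell, RPA43 (-0.41), RPA135 (-0.42) and RPA49 (-0.30), and 1 rose; adjusted over the list alone 8 fell and 2 rose (median -0.10, camera adjusted p = 0.00656, adjusted p = 0.233 with an estimated correlation). None of the 12 cohesin and loader genes passed in either count, SCC2 included (-1.57, SE 0.50, adjusted p = 0.0902), nor did HIS3 (1.19, SE 0.31, adjusted p = 0.0546). TIF5, a translation initiation factor, fell by 0.71 and RIM4, a meiotic RNA-binding protein, by 0.74.

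The meiosis and sporulation list, which marks another cell state, had 2 of 26 members higher, REC8, the meiotic kleisin of cohesin (9.76 ± 0.269 in WT to 14.0 ± 0.927, adjusted p = 0.0109), and ZIP1, of the synaptonemal complex (24.1 ± 1.89 to 35.9 ± 3.77, adjusted p = 0.0157); 3 rose when adjusted over the list alone. Its median was 0.17 (camera adjusted p = 0.00821, adjusted p = 0.233 with an estimated correlation), and it did not pass with quantile normalization. Of 61 genes of silent loci and subtelomeric families 4 rose, COS10 (0.66), COS5 (0.37) and the identical pair PAU1 and PAU14 (0.61), and 6 when adjusted over the list alone (camera adjusted p = 0.0316, adjusted p = 0.739 with an estimated correlation), a call that quantile normalization also ended. Among 73 snoRNAs snR50 rose (0.78, SE 0.16), in both counts the only call, and the median was 0.33 (camera adjusted p = 1.99e-05, adjusted p = 0.739 with an estimated correlation).

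In the G2/M list 2 of 35 members fell, the cyclin gene CLB4 (-0.34) and the eisosome gene SUR7 (-0.45), and 4 when adjusted over the list alone (median -0.23, camera adjusted p = 1.99e-05, adjusted p = 0.739 with an estimated correlation). Its median was -0.26 and -0.43 in libraries 1 and 3, and -0.01 in library 2. The M/G1 list had MCM2 (-0.31) and MCM3 (-0.24), of the replicative helicase, lower among 34, and 4 when adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.0155, adjusted p = 0.753 with an estimated correlation). By library that median was -0.16, 0.09 and -0.40, while that of ribosome biogenesis was -0.26, -0.18 and -0.34.

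Between the libraries labelled G1242V and WT 12 of 37 lists passed camera, 4 higher and 8 lower; with an estimated correlation 0 passed, and with fry 5. Limma called 279 features, 121 higher and 158 lower, with 7 higher and 4 lower by at least 2-fold; 1640 had an unadjusted p under 0.05, where 305 were expected by chance, and 2463 (40.4%, where chance gives 10%) did not overlap. The largest rise was of YLR466C-B, a feature outside the reference annotation (log2 fold 3.34, SE 0.57), and the largest falls were of 25S and 18S ribosomal RNA (-2.91 and -2.66). The RNA quality and depletion list had 4 of 15 members lower, and 12 when adjusted over the list alone (median -1.07, camera adjusted p = 4.55e-06, adjusted p = 0.584 with an estimated correlation). Of the 279 calls, 6 were of features with values identical to those of another feature. Copies of 1 ribosomal RNA locus may thus be counted repeatedly in this list. The count was 7 without libraries 1 and 3 labelled G1242V, which leaves library 2 alone against WT, 57 with TPM as deposited (39 higher), and 823 with only the 2 groups fitted. Leaving out 1 library gave 3 without WT library 1, 55 without WT library 2, 50 without WT library 3, 68 without library 1 and 4 without library 3 labelled G1242V, and 318 without library 2.

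R787G compared with empty_vector asks what the mutant protein still provides. By fold, the 5 largest rises in R787G that met the rule for named genes were led by SCC2 (2.79, SE 0.50). That difference is set by the plasmids, since the empty one holds no SCC2. The others were the daughter-cell gene DSE1 at 83.3 ± 6.89 against 22.1 ± 4.48 (log2 fold 1.88, adjusted p = 0.0247), DSE4 at 108 ± 15.1 against 31.1 ± 5.96 (1.77), SCW11 at 54.8 ± 8.43 against 16.2 ± 2.46 (1.70), and CTS1, the chitinase, at 295 ± 49.7 against 93.1 ± 17.6 (1.66). VEL1 (-2.44, SE 0.54), HIS3 (-1.38, SE 0.31) and NRG2 (-0.83, SE 0.18) were lower. In the G2/M list 17 of 35 members were higher and none lower, and 23 were higher and 1 lower when adjusted over the list alone (median 0.42, camera adjusted p = 1.07e-12, adjusted p = 0.448 with an estimated correlation). The M/G1 list had 11 of 34 higher, and 19 when adjusted over the list alone (median 0.26, camera adjusted p = 4.91e-10, adjusted p = 0.448 with an estimated correlation). RNA quality and depletion features (ribosomal RNA, its spacers and other abundant RNAs) also passed, with a median of 0.42 over 15, none called and 4 higher when adjusted over the list alone (camera adjusted p = 0.0174, adjusted p = 0.799 with an estimated correlation). So did the mitochondrial genome, with a median of 0.73, 4 of 24 higher and 17 when adjusted over the list alone (camera adjusted p = 4.91e-10, adjusted p = 0.448 with an estimated correlation). Relative to WT its median was -1.10 in empty_vector library 3, which stood apart from libraries 1 and 2 (-0.23 and -0.17), and 0.11 to 0.16 in R787G.

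Limma called 144 features in this comparison, 106 higher and 38 lower in R787G, with 28 higher and 4 lower by at least 2-fold; 1409 had an unadjusted p under 0.05, and 1452 (23.8%, where chance gives 10%) did not overlap. TPM as deposited, which shifts the median of all genes by -0.16, gave 69 higher and 219 lower. Without R787G library 1 the count was 415; it was 0 without R787G library 2 or 3 or empty_vector library 2, and 1 without empty_vector library 1 or 3.

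In the libraries labelled G1242V, 5 genes were higher than in empty_vector: TOS3, a kinase upstream of Snf1 (86.3 ± 15.1 against 42.2 ± 2.12), YPL014W (122 ± 20.6 against 51.0 ± 9.80), SET6, which overlaps ATG29 (log2 fold 0.87, SE 0.12), the transcription factor gene COM2 (227 ± 38.2 against 124 ± 7.26) and CUR1, a protein-sorting factor (log2 fold 0.71, SE 0.11). The 4 lower genes were YNR014W (-0.94), YMR194C-A (-0.83), MDY2, of tail-anchored protein insertion (-0.36), and TES1, a peroxisomal thioesterase (-0.35). These 9 limma calls stood beside 1127 features with an unadjusted p under 0.05, and 1590 (26.1%, where chance gives 10%) did not overlap. Of 37 lists 15 passed camera, 10 higher and 5 lower; with an estimated correlation 0 passed, and with fry 1. The mitochondrial genome was higher by a median of 0.67, with none of 24 called and 15 when adjusted over the list alone (camera adjusted p = 1.72e-09, adjusted p = 0.657 with an estimated correlation), again with empty_vector library 3 apart. The G2/M list had a median of 0.15, with none of 35 called and 10 higher when adjusted over the list alone (camera adjusted p = 4.82e-05, adjusted p = 0.657 with an estimated correlation). Relative to WT, library 3 labelled G1242V (-0.43) lay within the empty_vector libraries (-0.51 to -0.41). So that difference rests on libraries 1 and 2 (-0.26 and -0.01). Gcn4 targets had a median of -0.15, with none called in either count (camera adjusted p = 9.78e-08, adjusted p = 0.657 with an estimated correlation). The count of called genes was 94 without libraries 1 and 3 labelled G1242V, again library 2 alone, 30 without library 1, 25 without library 3, and 0 without library 2, without any of the empty_vector libraries, or with TPM as deposited, which shifts the median of all genes by -0.12.

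Set directly against each other, R787G and the libraries labelled G1242V gave no limma call, with 1228 features at an unadjusted p under 0.05; 1435 (23.5%, where chance gives 10%) did not overlap. RTT102, a chromatin remodelling subunit, was at 89.1 ± 4.11 in R787G against 110 ± 1.25, and PRP42, a splicing factor, at 30.3 ± 1.79 against 37.5 ± 1.66. The snoRNA snR77 had a log2 fold of -0.92 (SE 0.16). These, YMR320W and YMR103C had the smallest p (adjusted p = 0.117). The G2/M list had a median of 0.24 (camera adjusted p = 1.17e-06, adjusted p = 0.738 with an estimated correlation), with no member called over all genes and 4 higher when adjusted over the list alone. Relative to WT that list stood at -0.26, -0.01 and -0.43 in the libraries labelled G1242V and between -0.02 and 0.06 in R787G, so the difference rests on libraries 1 and 3. RNA quality and depletion features had a median of 0.60, with none called in either count (camera adjusted p = 0.00718, adjusted p = 0.774 with an estimated correlation). Without R787G library 1 the count was 135, without library 2 labelled G1242V 74, and without library 1 labelled G1242V 3.

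Effects against WT were then compared across genes, which are not independent replicates. For the libraries labelled G1242V and empty_vector, Pearson's r was 0.694 and Spearman's rho 0.628, where simulated groups that share the WT libraries and have no effect gave 0.498 and 0.458. Among called genes 23 rose in both, 22 fell in both and 0 went opposite ways, an overlap that the shared WT libraries favour and that was not simulated. Library 3 labelled G1242V, whose label is left undecided below, had the SCC2 and HIS3 levels of empty_vector. If that label is wrong, the likeness of these groups is in part that of empty_vector with itself. R787G and G1242V gave r = 0.515 (simulated 0.496) but rho = 0.445 (simulated 0.456), with the same sign at 65.6% of features (simulated 66.6%). R787G and empty_vector gave r = 0.336 (simulated 0.498) and rho = 0.358 (simulated 0.458). The simulations draw independent libraries, while R787G libraries share deviations with the WT libraries of equal number, so small differences from them decide nothing for R787G. The simulations also give neither group an effect. An effect in only 1 group, unrelated to the other, widens its folds and lowers r and rho but not the covariance. So r and rho under the simulated values do not show that R787G goes against empty_vector. The covariance was 0.0505 against a simulated 0.0119 for G1242V and empty_vector, 0.0220 against 0.0119 for R787G and G1242V, and 0.0155 against 0.0118 for R787G and empty_vector. Along the empty_vector effect the slope was 0.707 for the libraries labelled G1242V and 0.0652 for R787G. Before the pooled variance was removed, these slopes were 0.644 and 0.197, so the value for R787G depends on that estimate. By library the slope after removal was 0.898, 0.233 and 1.01 for the libraries labelled G1242V and 0.428, 0.175 and -0.364 for R787G. Leaving out 1 library moved it from 0.565 (without library 3) to 0.943 (without library 2) for G1242V and from -0.154 (without WT library 3) to 0.302 (without R787G library 3) for R787G.

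**Figure D3:**
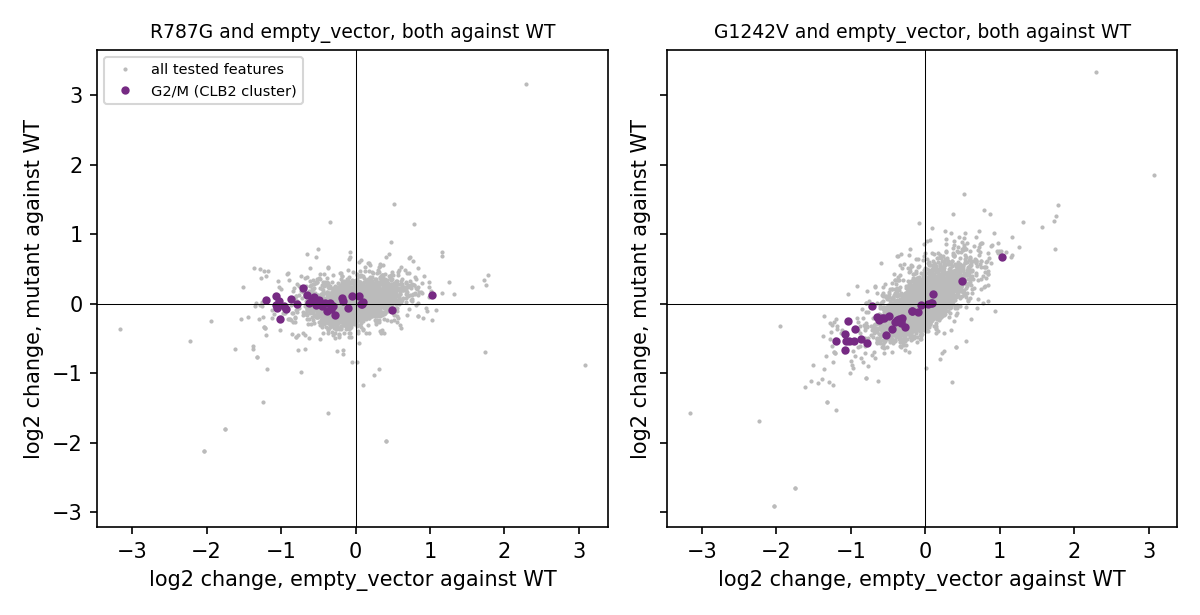
Log2 fold change against WT of each tested gene, with empty_vector on the x axis and R787G or the libraries labelled G1242V on the y axis, and the genes of the G2/M list in purple. The slope along the empty_vector effect is 0.0652 for R787G and 0.707 for the libraries labelled G1242V.

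Position along the chromosome was tested because cohesin is dense around centromeres and its loader binds near tRNA genes. Neither the 395 genes near centromeres nor the 352 next to tRNA genes passed in a comparison against WT (camera adjusted p of 0.665 or more in each). The 254 genes near chromosome ends were higher in R787G, with a median of 0.07 (camera adjusted p = 0.000121, adjusted p = 0.0230 with an estimated correlation), though no single one was called. Their median was 0.06 in the libraries labelled G1242V (adjusted p = 0.0800) and 0.03 in empty_vector (adjusted p = 0.733). Within 10 kb of an end the libraries labelled G1242V passed as well, with a median of 0.101 (genes near chromosome ends, G1242V against WT) beside 0.0906 (genes near chromosome ends, R787G against WT). Within 50 kb the medians were 0.0155 in R787G, which still passed, and 0.0145 in the libraries labelled G1242V, which did not. Set directly against each other at 25 kb, the groups did not differ past the threshold. R787G had a median of 0.02 against the libraries labelled G1242V (camera adjusted p = 0.838) and 0.06 against empty_vector (camera adjusted p = 0.342). The libraries labelled G1242V had a median of 0.06 against empty_vector (camera adjusted p = 0.314). With an estimated correlation, run at 25 kb, the chromosome-end set held in R787G against WT. It did not pass in the libraries labelled G1242V against WT (adjusted p = 0.279). These values are adjusted over the position sets alone, so they are not comparable with those of the gene lists. The chromosome-end set was rerun only with other windows and with an estimated correlation, not with other scalings or with libraries left out. In the gene list of silent loci and subtelomeric families, the median by R787G library was 0.146, 0.175 and 0.000334, so library 3 showed no rise there.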

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

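Tests chosen only after the result was seen were those without libraries 1 and 3 labelled G1242V, without any library labelled G1242V in the fit, with identical features counted once, and fry. Of the 40 list calls against WT, all kept their direction in TPM as deposited (39 stayed past the threshold), quantile normalization (36) and a replicate block (40). With an estimated correlation none of the 40 passed, and fry kept 9. Counts stayed within 1.5 times their value with pseudocounts of 0.1 and 5, protein-coding genes only, a filter at a mean TPM of 10, a robust variance and identical features counted once. The files hold no counts, so what depth limits is not known. Leaving out a library also leaves fewer samples; otherwise the cause was not tested.

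With TPM as deposited the count of changed genes was 57 for G1242V against WT (39 higher, 18 lower), 288 for R787G against empty_vector (69 higher, 219 lower) and 0 for G1242V against empty_vector, and the log2 fold of RAD61, R787G against WT, was -0.0459. For empty_vector against WT the count was 0 with no filter, 0 with a replicate block and 0 with no variance trend. R787G against empty_vector gave 68 with the block, 95 with no trend and 80 with only the 2 groups; G1242V against empty_vector gave 14 with the block and 0 with only the 2 groups. Fitting only the 2 groups gave 3 for R787G against WT and 823 for G1242V against WT.

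Without libraries 1 and 3 labelled G1242V the count was 5 for R787G against WT, 7 for G1242V against WT and 94 for G1242V against empty_vector. Library 2 is then the only one of its group, so its spread comes from the other groups alone. Log2 folds there were 0.0895 for MCD1, G1242V against WT, and -0.0365 for IRR1, G1242V against WT; the M/G1 median in that comparison was 0.0927, and R787G against G1242V had 5 lists. Without any library labelled G1242V in the fit, R787G against WT gave 5. Lists with an estimated correlation numbered 0 in each of the 6 comparisons. With fry they numbered 0 for R787G against WT, 5 for G1242V against WT, 7 for empty_vector against WT, 6 for R787G against empty_vector, 1 for G1242V against empty_vector and 0 for R787G against G1242V.

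Leaving out 1 library at a time, counts ranged from 3 to 318 for G1242V against WT, 0 to 24 for empty_vector against WT, 0 to 415 for R787G against empty_vector, 0 to 30 for G1242V against empty_vector and 0 to 135 for R787G against G1242V. Log2 folds ranged from -0.0875 to 0.0732 for SCC4, R787G against WT, from -0.0713 to 0.0212 for SMC1, R787G against WT, and from -0.0309 to 0.0188 for PDS5, R787G against WT. They ranged from -0.0169 to 0.0399 for RAD61, R787G against WT, and from -0.00161 to 0.164 for RAD61, empty_vector against WT; none of these was called. Position medians in G1242V against WT were 0.0114 near centromeres and 0.101 near chromosome ends (adjusted p = 0.0151) in the 10 kb window. In empty_vector against WT they were -0.0334 near centromeres at 10 kb, -0.0109 at 50 kb and -0.0171 next to tRNA genes at 0.5 kb, and in R787G against WT -0.00195 next to tRNA genes at 2 kb.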

Other observations

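Tests on the unequal SCC2 levels and on ribosomal RNA were chosen only after the result was seen; the matched lists and the splits of the samples were set before. Mitochondrially encoded genes were lower in empty_vector than in WT, with a median of -0.52 over 24 features (camera adjusted p = 5.81e-06, adjusted p = 0.440 with an estimated correlation). SCEI, the omega intron endonuclease, was the only call, at 21.4 ± 5.03 against 47.7 ± 9.91 (SD, n = 3), and adjusted over the list alone 4 were lower. By library the median was -0.23, -0.17 and -1.10, the last in the library with the lowest SCR1 share, 7.07%. The iron regulon of Aft1 had a median of 0.17 in empty_vector, with no member of 24 called and 3 higher when adjusted over the list alone (camera adjusted p = 0.000181, adjusted p = 0.440 with an estimated correlation). TIS11, which destabilises mRNAs in iron shortage, was at 59.7 ± 19.6 against 25.7 ± 5.48 (adjusted p = 0.0581).

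DNA damage response genes included 3 of 27 lower in empty_vector. Among them were ALK1, a call already counted in the G2/M list, and DUN1, a checkpoint kinase (13.9 ± 0.780 against 21.4 ± 0.533). Adjusted over the list alone 4 were lower and 2 higher (median -0.21, camera adjusted p = 0.0336, adjusted p = 0.442 with an estimated correlation). Markers of the opposite mating type had medians of 0.15, 0.34 and 0.11 over 5 genes in R787G, the libraries labelled G1242V and empty_vector, and passed in none (adjusted p = 0.218, 0.0508 and 0.483). In R787G glucose-repressed and hexose transport genes had a median of 0.17, with no member called in either count (camera adjusted p = 7.57e-06, adjusted p = 0.378 with an estimated correlation); ICL1, of the glyoxylate cycle, was at 41.6 ± 3.37 against 31.3 ± 1.27.

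SCC2 and HIS3 RNA were unequal among the libraries labelled G1242V: the highest SCC2 level was 7.50 times the lowest, against at most 1.17 in the other groups. Loss of the whole plasmid is argued against, because HIS3, its marker, was in libraries 1 and 3 at least 1.85 times the highest level of WT and R787G, where it varied by at most 1.55 times within a group. A wrong label on library 3 may account for its levels but is left undecided. Over 100 genes chosen without it, its median position between empty_vector (0) and G1242V (1) was 0.354. That lies within the held-out empty_vector libraries (-0.07 to 0.48), though their range is wide, and libraries 1 and 2 stood at 0.515 and 0.950. On the first principal component library 3 (10.3) and library 1 (9.19) lay among the empty_vector libraries (6.85 to 16.6). On the second, library 3 (-4.96) lay outside them (-0.974 to 18.6), on the side of libraries 1 and 2 (-7.07 and -9.73). A mixture of cells with and without the SCC2 insert was left undecided, since the shares read from SCC2 and HIS3 in library 1 differed by 0.291 (0.520 and 0.811) while those in library 3 agreed (1.00 and 0.968). An effect of G1242V on SCC2 RNA that differs between cultures stays open, untested.

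Ribosomal RNA of 25S and 18S was lower outside WT, in R787G by log2 folds of -2.12 and -1.80, which did not pass, and in the libraries labelled G1242V (-2.91 and -2.66) and empty_vector (-2.03 and -1.75), which did. Less ribosomal RNA made, as the whole cause, is argued against for 25S in R787G and the libraries labelled G1242V. There 25S was lower by more than the 5' external spacer of its precursor, by -1.79 (SE 0.364) and -2.22 (SE 0.532). In empty_vector the extra fall was the smallest, -0.802 (SE 0.319). That is past the limit of 2 SE set for the test, but with 3 libraries per group it does not settle the question there. For 18S the comparison with the spacer was not tested, and in empty_vector the log2 fold of 18S (-1.75) lay nearer to that of the spacer (-1.23). More complete removal of ribosomal RNA from the libraries outside WT could give the extra fall of 25S, and stays open because the labels give no library batches. A lower level of precursor in addition stays open for empty_vector, where the spacer itself had a log2 fold of -1.23 (adjusted p = 0.0491).

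Ribosome biogenesis genes lay below WT in all 3 groups. GC content, length and expression level are argued against: among 10000 random lists matched on them, with values for 97 of 97 members, the list's median was at percentile 0 in each comparison, at -0.16, -0.26 and -0.16 in R787G, the libraries labelled G1242V and empty_vector against lowest random medians of -0.04, -0.06 and -0.07. Culture density at harvest, given only as a range of OD600 for all cultures, could differ between groups and was not tested, and an effect of the Scc2 changes stays open as well. All 3 comparisons share the WT libraries, so they do not count as separate evidence.

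The 6 libraries of each comparison can be split 10 ways, too few for a share under 0.05. The real split and the highest other called 279 and 0 genes for G1242V against WT, 161 and 0 for empty_vector against WT, 144 and 5 for R787G against empty_vector, and 9 and 0 for G1242V against empty_vector, so that 1 of 10 splits reached the real count in each. For R787G against WT and R787G against G1242V each of the 10 splits called 0 genes.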
